A study of Mus musculus with 16 samples.

How the data were processed

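Total RNA of gastrocnemius and triceps had been extracted with Trizol and purified on RNeasy columns, its quality had been checked on a BioAnalyzer, and biotin-labelled cRNA had been made from 4 ug of it, per the labels' protocols. Each of the 16 samples was hybridised to an Affymetrix mouse expression array, on which several short probes form a probe set for a transcript. The deposited table gives 1 log2 value per probe set and array. MAS5 is the only tool that the submitters' processing notes name, with no version. The scaling target, the rule by which the table came to hold only 7729 probe sets, and any further normalization are not given in the sources used here. No source states the base of the logarithm. Base 2 was read from the values, which range from -0.773 to 14.81, because another common base would put the highest signals beyond what a scanner can record.

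The table holds 0 control probe sets. Undone to the linear scale, the mean of each array between its 2nd and 98th percentile of signal differed by 1.06-fold at most, under the limit of 1.2 set for rescaling, so the values were used as deposited. A pseudocount of 16 had been planned for a linear table and was not used, since the table is already on a log scale. For arrays no depth can be given, and the number of arrays limits the precision. Gene symbols came from the platform annotation. A single symbol was given for 7053 probe sets, several for 330 and none for 346, and only the first kind were named. The Entrez identifiers of 7048 of them were found among the RefSeq genes of assembly GRCm38.p6, which changed 0 symbols. No genome build belongs to the table, and no coordinates are given.

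Probe sets with a mean over all 16 arrays above the 40th percentile (log2 6.75) were tested, 4637 in all. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 4 groups (lmFit, and eBayes with an intensity trend), so that all groups shared an estimate of the spread. The comparisons were SOD1-G93A against NTg in gastrocnemius, in triceps and averaged over both muscles, the difference of the genotype effect between the muscles, and gastrocnemius against triceps. The design was the authors' own for the genotypes, and the last comparison used its other factor. Differences are SOD1-G93A minus NTg or gastrocnemius minus triceps, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. For the averaged comparison of single probe sets the mouse was a random block (duplicateCorrelation, consensus correlation 0.18). The gene list tests had no such block, so in them both muscles of a mouse counted as separate samples. Groups, the tests of probe sets and of gene lists, the lists themselves and the rule for named genes were fixed before the data were examined.

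The series states that both muscles came from 4 mice of each genotype, and replicate numbers were taken to mark the mouse. In deviations from the group means, the 2 muscles with the same genotype and number correlated at 0.14 to 0.39 across probe sets, and in 8 of 8 cases a gastrocnemius array correlated best with the triceps array of its own number. Tests of single values per array or per mouse were exact permutation tests, chosen after the results they concern were seen.

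Of 29 gene lists written for muscle, its metabolism, stress responses, ALS and the other cell types of a muscle sample, 25 had at least 3 tested members and were tested with camera (limma), at a preset correlation between genes of 0.01, on 3034 genes with 1 probe set each (the brightest over all arrays). The minimum of 3 was chosen after the list sizes were seen. Adjustment was over the 25 lists within a comparison, and an estimated correlation was the alternative. Some genes stand on more than 1 list: Gpd1 is on the adipocyte, fast fibre and glycolysis lists, and Atp2a2 is on the slow fibre and calcium-handling lists. The adipocyte list also holds genes that muscle fibres express, such as Car3 and Gpd1.

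The genes named are, per genotype comparison, the 10 per direction with the largest differences among those called, filled up with those of smallest unadjusted p where fewer passed, for the muscles the 10 largest called per direction, for the difference of effects the 5 of smallest p per direction, in each comparison Sod1 and the 3 members of smallest p of each list. The text names part of these. Ckm, Acta1, Pvalb, Adipoq and Fabp4 where they fall outside the rule, and the genes given for replicate numbers, were chosen after their values were seen.

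The fits were tested on simulated data with the real arrays' spread, in which 200 of 4637 probe sets were changed by 1.5-, 2- or 4-fold. Simulated probe sets varied independently, with equal spread in all groups, no odd arrays and no shift between replicate numbers. So many changed probe sets ease the adjustment, and recovery can be lower where fewer genes change. Of the 4-fold changes 98.5% were recovered in gastrocnemius, 97% in triceps, 100% over both muscles, 98.5% for the difference of effects and 100% between muscles, and 3.7%, 5%, 3.98%, 0.98% and 2.25% of the calls were of unchanged probe sets. Alternatives fixed beforehand were added constants of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median centring, other variance models, array weights, 1 probe set per gene, replicate blocks, subsets of the samples and leaving out each array. Added after the data were seen were a constant of 16, leaving out the 3 triceps arrays with low muscle transcripts, and a split of the arrays into replicates 1 and 2 and replicates 3 and 4.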

Results

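Expression was measured in 2 limb muscles of female C57BL/6 mice aged 7 weeks, a stage that the series describes as presymptomatic. The transgenic mice carried human SOD1 (superoxide dismutase 1, a cytosolic antioxidant enzyme) with the G93A substitution. They are a widely used model of amyotrophic lateral sclerosis (ALS), a disease in which motor neurons die and muscles lose their nerve supply. Their controls were non-transgenic (NTg) mice. Gastrocnemius, a calf muscle of the hindlimb, and triceps, a muscle of the upper forelimb, were taken from 4 mice of each genotype, which gave 16 arrays in 4 groups of 4. Array medians lay between 7.10 and 7.26 on the log2 scale. The table holds 7729 probe sets, which is only part of such an array, and 4637 of them were bright enough to be tested. 3 of the triceps arrays stood apart, a choice made after their values were seen. In NTg triceps replicates 1 and 2 and in SOD1-G93A triceps replicate 2, Ckm, which encodes muscle creatine kinase, was at 12.84, 13.02 and 12.76, while the other triceps arrays lay between 13.84 and 14.51.

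No genotype difference in Sod1 passed the test. Its level was 11.32 ± 0.30 (SD, n = 4) in SOD1-G93A gastrocnemius and 11.15 ± 0.15 in NTg gastrocnemius, and 10.91 ± 0.44 in SOD1-G93A triceps against 10.62 ± 0.69 in NTg triceps. The difference was 0.18 in gastrocnemius and 0.28 in triceps, with a standard error (SE) of 0.27 in each, and limma's adjusted p was 0.999 and 0.994. The probe set is annotated to the mouse gene, and whether it also reads the human transcript is not known here, so it checks no label.

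The first comparison asked what the SOD1-G93A transgene changes in gastrocnemius before symptoms. Adipocyte markers were higher in SOD1-G93A gastrocnemius, with a median log2 difference of 0.44 over 7 tested members, all 7 of them above 0. This list has 22 members, of which 10 were in the table, and it includes genes of lipid synthesis. The list passed the competitive test camera (limma) at adjusted p = 6.06e-06, and missed the threshold at adjusted p = 0.0549 with an estimated correlation. Fasn, which encodes fatty acid synthase, had the largest difference of these at 1.72 (SE 0.41), a 3.29-fold higher signal (7.53 ± 0.74 against 5.81 ± 0.78, SD, n = 4). Its NTg mean lay under the filter level of 6.75, so this fold rests partly on a dim signal. Scd1, which encodes a desaturase that makes monounsaturated fatty acids, was at 0.99 (SE 0.39), and Thrsp, a gene of lipogenic tissues, at 0.63 (SE 0.33). With single arrays left out the list's median lay between 0.31 and 0.68 (camera's adjusted p up to 0.00561), highest without SOD1-G93A gastrocnemius replicate 4. No member passed over all probe sets, and 1 (Fasn) passed adjusted over the list alone.

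No single probe set passed the test in gastrocnemius. limma called 0 of 4637 probe sets, while 103 had an unadjusted p under 0.05, 41 of them higher and 62 lower in SOD1-G93A, where chance alone would give about 232. After Fasn, the genes with the smallest p among those with higher values included Nkiras2 (0.86), an inhibitor of NF-kappaB signalling, and Golga2 (0.58), a Golgi matrix protein. Others were Ddx6 (0.56), an RNA helicase of processing bodies, and Inpp5a (0.50), an inositol phosphatase. Among lower values were Bcl6 (-0.85), a transcriptional repressor, Brox (-0.79), Insig2 (-0.69), which restrains sterol and lipid synthesis, Aox1 (-0.60), Mprip (-0.64), Tmem30a (-0.59) and Vldlr (-0.45), a lipoprotein receptor. None of these passed, each with an adjusted p of 0.999. The median SE of 0.197 put the 95% interval of a typical probe set at 1.33-fold either way, and in data simulated at this spread 71.6% of 2-fold changes and 25.4% of 1.5-fold changes were recovered. Those data held 200 changed probe sets and no odd arrays, so recovery in the real arrays may be lower. Fasn, at 3.29-fold, did not pass here (limma's adjusted p = 0.999). The mean of the adipocyte list was 0.62 higher in SOD1-G93A gastrocnemius (exact permutation p = 0.0857, two-sided), 0.791 within mice numbered 1 and 2 and 0.449 within those numbered 3 and 4. That permutation test was chosen after the list's result was seen.

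In triceps, the same question gave 3 gene lists with higher values in SOD1-G93A by camera, and none of these calls held with an estimated correlation. For slow fibre, extracellular matrix and adipocyte genes the adjusted p was 0.00114, 0.00114 and 0.00314, against adjusted p = 0.758, 0.758 and 0.513 with an estimated correlation. Slow fibre genes, the contractile and calcium-handling genes of oxidative type I fibres, had a median difference of 0.69 over 14 members, 12 of them above 0. Examples were Tpm3 at 0.97 (SE 0.41, with other probe sets at 0.20 and 0.00), Atp2a2 at 0.84 (SE 0.42), which encodes the slow-type calcium pump of the sarcoplasmic reticulum, and Myoz2 at 0.68 (SE 0.28), a protein of the Z-disc. Extracellular matrix genes had a median of 0.18, with 26 of 27 members above 0, among them Eln (elastin) at 0.53 (SE 0.21) and Timp3, an inhibitor of matrix proteases, at 0.46 (SE 0.25). Adipocyte markers had a median of 0.43, with all 7 above 0, Fasn at 0.88 (SE 0.41), Scd1 at 0.87 (SE 0.39) and Adipoq, which encodes the fat hormone adiponectin, at 0.43 (SE 0.27). No member of these lists passed the test, over all probe sets or adjusted over the list alone.

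The slow fibre call ended without SOD1-G93A triceps replicate 4 (adjusted p = 0.544, median 0.26), without NTg triceps replicate 2 (0.059, median 0.38) and without SOD1-G93A triceps replicate 3 (0.0518). The matrix call ended without NTg triceps replicate 2 (0.331, median 0.06), without SOD1-G93A triceps replicate 1 (0.0612) and without the 3 arrays that stood apart (0.247, median 0.12), and its median was 0.30 without NTg triceps replicate 4. The adipocyte call ended without SOD1-G93A triceps replicates 1 (0.0612) or 2 (0.0646) and without those 3 arrays (0.281, median 0.14). Without those 3 arrays the oxidative phosphorylation list passed with lower values (adjusted p = 0.00608, median -0.07), against an adjusted p of 0.905, a median of 0.02 and adjusted p = 0.948 with an estimated correlation for all arrays.

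No single probe set passed in triceps either. limma called 0 of 4637 probe sets, with 118 at an unadjusted p under 0.05, 72 higher and 46 lower. Higher values with the smallest p included Gas6 at 0.53 (SE 0.15), a ligand of the TAM receptor kinases, Txnip at 0.47, an inhibitor of thioredoxin and of glucose uptake, and Rnf14 at 1.25. Others were Cacna2d1 at 1.09, a subunit of the muscle calcium channel, and Vapb at 1.03, a membrane-tethering protein whose gene is mutated in a familial form of ALS. Lower values included Hnrnpa1 (-0.66), an RNA-binding protein also mutated in rare ALS, Twf2 (-0.51), an actin-binding protein, and Psmd11 (-0.51), a proteasome subunit, followed by S100a1 (-0.37), a calcium sensor of muscle, and Park7 (-0.33), a protein that protects against oxidative stress. Each had an adjusted p of 0.994. Other probe sets of Rnf14 (-0.10) and Psmd11 (0.19, 0.06 and 0.04) pointed the other way. In simulated data 67.2% of 2-fold and 35.8% of 1.5-fold changes were recovered in this comparison. The mean of the adipocyte list in triceps was 0.449 higher in SOD1-G93A (exact permutation p = 0.0286, two-sided, the smallest possible), 0.701 within mice numbered 1 and 2 and 0.197 within those numbered 3 and 4. Here too the permutation test was chosen after the list's result was seen.

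Averaged over both muscles, the adipocyte markers were again higher in SOD1-G93A. Their median difference was 0.44, with 7 of 7 above 0, and camera (limma) gave an adjusted p of 4.15e-07 and an adjusted p = 0.0286 with an estimated correlation (0.0499 with the replicate set, numbers 1 and 2 against 3 and 4, as a block). Camera had no mouse block, so both muscles of a mouse counted as separate samples in these values. Without the 3 triceps arrays that stood apart the median was 0.29 (camera's adjusted p = 0.000811 at the preset correlation). Fasn was at 1.30 (SE 0.30), a 2.46-fold higher signal, Scd1 at 0.93 (SE 0.29), Thrsp at 0.56 (SE 0.24) and Adipoq at 0.43 (SE 0.20). Fabp4, an abundant fatty acid carrier of adipocytes, was at 0.09 (SE 0.13). No member passed over all probe sets, and 2 (Fasn and Scd1) passed adjusted over the list alone. The list mean per mouse was 9.97 ± 0.32 (SD) in SOD1-G93A and 9.43 ± 0.12 in NTg, with all 4 SOD1-G93A mice above the highest NTg mouse (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give). This test was chosen after the list's p was seen. Within mice numbered 1 and 2 the difference was 0.746, and within those numbered 3 and 4 it was 0.323.

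**Figure D1:**
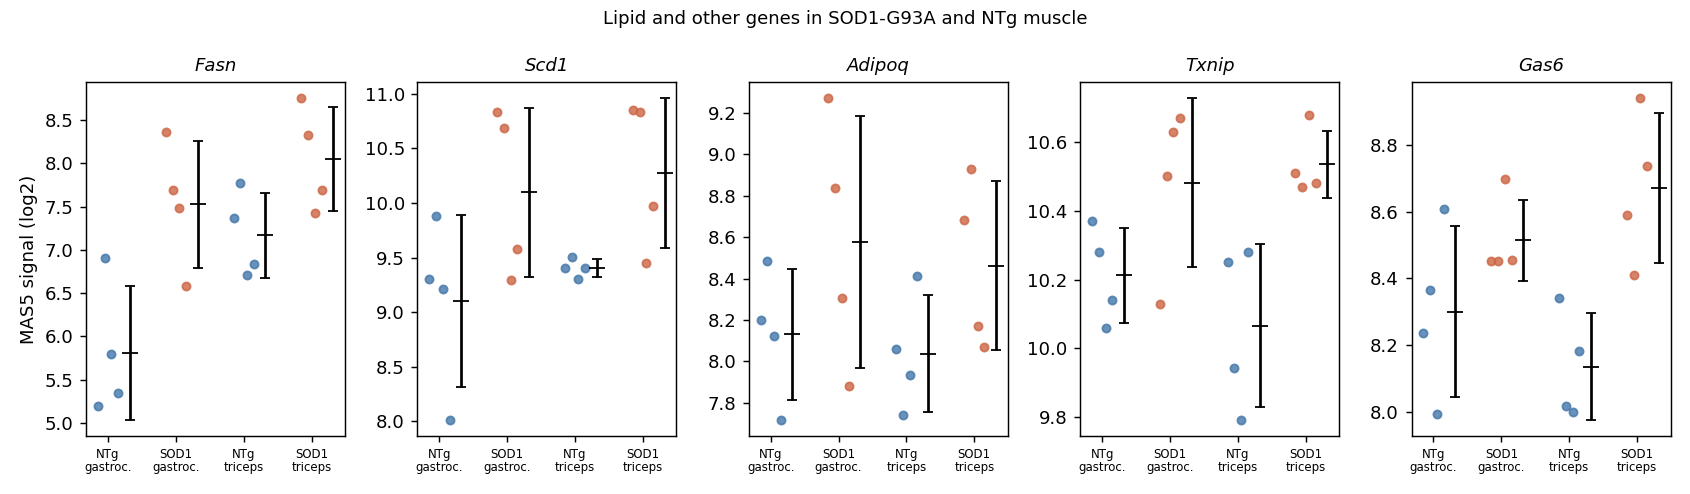
MAS5 signal on the log2 scale (vertical axes, each with its own range that does not start at 0) of Fasn, Scd1, Adipoq, Txnip and Gas6 in the 4 groups of muscle. Points are arrays, black bars give the mean and SD of 4 arrays, and Fasn averaged 7.53 in SOD1-G93A and 5.81 in NTg gastrocnemius, while none of the 5 genes passed the test over all probe sets.

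Over both muscles limma called 0 of 4637 probe sets, and 85 had an unadjusted p under 0.05, 37 higher and 48 lower. Besides Fasn and Scd1, higher values with the smallest p were found for Txnip (0.37), Gas6 (0.37), Eln (0.50), Egr1 (0.96), an immediate early transcription factor, and Dbp (0.36), an output gene of the circadian clock. Lower values were found for Twf2 (-0.53), Bcl6 (-0.72), Hnrnpf (-0.62), Hnrnpa1 (-0.50), Atp5md (-0.48), a small subunit of ATP synthase, and Tsc22d1 (-0.48). None passed, with an adjusted p of 0.997 for each. With the replicate set as a block, a setting added after the data were seen, limma again called 0 probe sets. The smallest adjusted p was then 0.0584, and 194 probe sets had an unadjusted p under 0.05. The median SE was 0.153, a 95% interval of 1.25-fold either way, and 94% of simulated 2-fold changes were recovered.

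The genes of 4 further lists had slightly higher values in SOD1-G93A over both muscles, in the same test without a mouse block. They were fast fibre genes (median 0.19, 18 of 18 above 0, adjusted p = 0.00633), genes of glycogen use and glycolysis (0.13, 18 of 22 above 0, 0.0385), circadian clock genes (0.14, 9 of 11 above 0, 0.0385) and calcium-handling genes (0.14, 18 of 25 above 0, 0.0475). None of the 4 held with an estimated correlation (adjusted p = 0.941 with an estimated correlation for fast fibre, glycolysis and calcium-handling genes, and adjusted p = 0.583 with an estimated correlation for clock genes), after quantile normalization (0.871, 0.403, 0.0821 and 0.322, in the order named, with the fast fibre median at -0.00144) or without the 3 triceps arrays that stood apart (0.295, 0.674, 0.482 and 0.539, with medians of 0.07, 0.03, 0.03 and 0.05). Without single arrays the lowest medians were 0.08 for fast fibre genes (NTg triceps replicate 1) and 0.08, 0.09 and 0.07 for glycolysis, clock and calcium-handling genes (NTg triceps replicate 2), and the highest for fast fibre genes was 0.35 (SOD1-G93A triceps replicate 2). No member passed the test, over all probe sets or adjusted over the list alone. All 4 calls also ended without NTg triceps replicate 1 (adjusted p from 0.181 to 0.325), NTg triceps replicate 2 (0.136 to 0.36), NTg gastrocnemius replicate 2 (0.0657 to 0.131), SOD1-G93A triceps replicate 3 (0.136 for each) or SOD1-G93A gastrocnemius replicate 4 (0.0544 to 0.114). Some of them ended without SOD1-G93A triceps replicate 4 (fast fibre 0.174, glycolysis 0.162, calcium 0.227), NTg gastrocnemius replicate 1 (glycolysis 0.0961, clock 0.0961, calcium 0.109), SOD1-G93A gastrocnemius replicate 2 (clock and calcium, 0.0981 each) or 3 (clock 0.102, calcium 0.172), with no filter on dim probe sets (glycolysis 0.0533, clock 0.103) and with the filter at the 60th percentile (glycolysis and clock, 0.0618 each, and calcium 0.124).

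The other lists did not pass the test over both muscles with all arrays. Slow fibre genes had a median of 0.22 and an adjusted p of 0.0808, which was 0.0236 without the 3 triceps arrays that stood apart (with all arrays, adjusted p = 0.941 with an estimated correlation), and myogenesis genes had an adjusted p of 0.175. For atrophy and autophagy genes, which include the ubiquitin ligases of wasting muscle, the median was 0.03 over 18 members (adjusted p = 0.737). For 15 other genes linked to ALS it was -0.03 (0.737), for 23 heat shock protein genes 0.01 (0.905, with the test pointing to lower values), and for 13 endoplasmic reticulum stress genes 0.02 (with the mean and the test pointing to lower values). Adjusted p values between 0.613 and 0.949 were found for these stress genes, for extracellular matrix, fatty acid oxidation, oxidative phosphorylation, citric acid cycle, antioxidant, proteasome, ribosomal protein, interferon and immediate early genes, and for markers of immune cells, Schwann cells, endothelium, smooth muscle and tendon. Of 30 genes of the neuromuscular junction and of denervation, 8 were in the table and 1 was bright enough to test (Prkar1a, -0.08, SE 0.14). The list was therefore not tested, nor were the erythroid markers, with 2 tested genes, or the lists of limb position genes, with 0 in the table.

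The genotype difference was then compared directly between gastrocnemius and triceps. Slow fibre genes (median of the difference in differences -0.91, 12 of 14 below 0) and extracellular matrix genes (-0.29, 26 of 27 below 0) had a lower SOD1-G93A effect in gastrocnemius than in triceps, and proteasome subunit genes a higher one (0.12, 22 of 31 above 0). Adjusted p values by camera (limma) were 0.00723, 0.000151 and 0.0108, and no call held, at adjusted p = 0.882, 0.882 and 0.844 with an estimated correlation. Examples were Atp2a2 at -1.12 (SE 0.60) and Tpm3 at -1.10 (SE 0.58) among slow fibre genes, Lum at -0.83 (SE 0.40), Col3a1 at -0.58 (SE 0.28) and Col6a3 at -0.52 (SE 0.20), a collagen VI chain, among matrix genes, and Psma5 at 0.40 (SE 0.20) among proteasome genes. The slow fibre value rests partly on triceps signals near the bottom of the scale. No member passed the test, over all probe sets or adjusted over the list alone. The adipocyte list did not pass this test (median 0.06, adjusted p = 0.381).

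limma called 0 probe sets for this difference, with 86 at an unadjusted p under 0.05, 27 higher and 59 lower. Genes with the smallest p were Mrpl11 (1.14), a mitochondrial ribosomal protein, Nkiras2 (0.93), Golga2 (0.89), Ddx6 (0.73) and Zcchc17 (0.66) above 0. Below 0 they were Nras (-1.46), a small GTPase, Marcks (-0.94), Tmem167 (-0.79), Cep68 (-0.74) and Septin7 (-0.70), each with an adjusted p of 0.999. A further probe set was at 0.04 for Marcks and at 0.00 for Septin7. Recovery in the simulated data was lowest here, at 47.8% of 2-fold changes. The slow fibre call ended without SOD1-G93A triceps replicates 4 (0.421, median -0.45) or 3 (0.0942), NTg triceps replicate 2 (0.0993, median -0.49) or SOD1-G93A gastrocnemius replicate 1 (0.134). The matrix median was -0.16 without NTg triceps replicate 2 and -0.46 without NTg triceps replicate 4. The proteasome call ended without SOD1-G93A gastrocnemius replicate 1 (0.134, median 0.08), SOD1-G93A triceps replicate 1 (0.0609), NTg triceps replicate 2 (0.0583), NTg gastrocnemius replicate 3 (0.0539, median 0.08), the 3 arrays that stood apart (0.112, median 0.02), with quantile normalization (0.128) or with no filter on dim probe sets (0.0504).

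The muscles themselves differed strongly, whatever the genotype. Gastrocnemius had far higher levels of the genes of slow, oxidative fibres: all 14 tested members of the slow fibre list rose over triceps, with a median log2 difference of 4.08. Myh7, the slow myosin heavy chain, was 6.91 higher (SE 0.80, adjusted p = 2.77e-05), at 11.11 ± 0.24 in NTg gastrocnemius and 3.16 ± 2.16 in NTg triceps (SD, n = 4). The slow light chains Myl2 (5.87) and Myl3 (5.25), the slow troponins Tnnt1 (5.78), Tnni1 (5.58) and Tnnc1 (4.68), slow tropomyosin Tpm3 (4.90, with another probe set at 0.18), the calcium pump Atp2a2 (4.02) and Myoz2 (3.24, adjusted p = 1.95e-08) were higher too. In triceps Myh7 went down to 1.30, Tnnt1 to 1.41 and Myl2 to 3.72, while 2% of an array's probe sets lay under a level of 3.63 to 4.84. Tnni1 averaged 4.27 in SOD1-G93A and 4.37 in NTg triceps, and Tpm3 4.98 in each. The sizes of these differences therefore rest on signals at the bottom of the scale, and their order is not to be read. By camera (limma) the slow fibre list had an adjusted p of 2.66e-34 and an adjusted p = 0.0178 with an estimated correlation (0.0287 with the replicate set as a block), and 14 of 14 members also passed adjusted over the list alone.

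**Figure D2:**
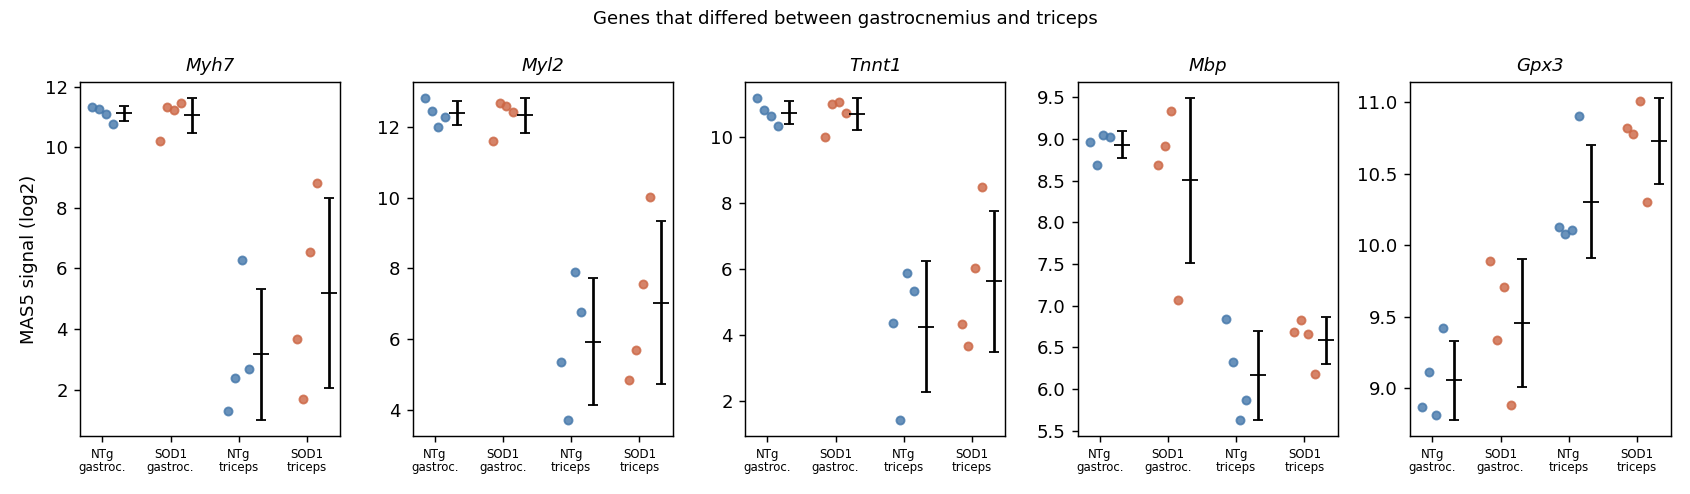
MAS5 signal on the log2 scale (vertical axes, each with its own range that does not start at 0) of Myh7, Myl2, Tnnt1, Mbp and Gpx3 in the 4 groups of muscle. Points are arrays, black bars give the mean and SD of 4 arrays, and the slow fibre genes Myh7, Myl2 and Tnnt1 and the myelin gene Mbp were higher in gastrocnemius, and Gpx3 was higher in triceps.

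Of the genes of myelinating Schwann cells, 2 rose as well. Mbp, myelin basic protein, was 2.34 higher in gastrocnemius (SE 0.26) and Pmp22, peripheral myelin protein, 1.26 higher (SE 0.13), and Prnp, at 0.29 (SE 0.09), missed the threshold over all probe sets (adjusted p = 0.0961). The list of 3 tested nerve markers had a median of 1.26 and an adjusted p of 8.95e-06 (adjusted p = 0.0192 with an estimated correlation, which missed the threshold at 0.066 with the replicate set as a block), with 2 members past the threshold over all probe sets and 3 adjusted over the list alone. Tendon markers had a median of 0.45 over 3 members (adjusted p = 0.00753, and adjusted p = 0.287 with an estimated correlation), of which Fmod, a collagen-binding proteoglycan, rose by 0.66 and passed over all probe sets, and all 3 passed adjusted over the list alone. Of 27 extracellular matrix genes, 2 rose, Col1a1 by 1.31 and Fn1 (fibronectin) by 0.63, and 5 adjusted over the list alone (list median 0.14, adjusted p = 0.00855, and adjusted p = 0.646 with an estimated correlation). Smooth muscle markers had a median of 0.21 over 8 members, with Myl9 (0.76) past the threshold and 2 members adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.289 with an estimated correlation). The matrix call ended without NTg triceps replicate 2 (0.0599, median 0.09) and without the 3 triceps arrays that stood apart (0.346, median 0.00208). The smooth muscle call ended after quantile normalization (0.0533) and with the filter at the 60th percentile (0.0748).

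Some metabolic gene lists passed with higher values in gastrocnemius by camera, and none of these calls held with an estimated correlation. Of 25 fatty acid oxidation genes, 5 rose over all probe sets and 11 adjusted over the list alone, among them Fabp3, the fatty acid carrier of muscle, by 0.91 (SE 0.17), Lpl, lipoprotein lipase, by 0.69 (SE 0.10) and Acadm, a dehydrogenase of medium-chain fatty acids, by 0.43 (SE 0.10). The list had a median of 0.24 and an adjusted p of 5.11e-06, with an adjusted p = 0.287 with an estimated correlation. Of 22 genes on the citric acid cycle list, 3 rose both over all probe sets and adjusted over the list alone, Idh2 by 1.14, Mdh1 by 0.51 and Ckmt2, a mitochondrial creatine kinase, by 0.41 (median 0.08, adjusted p = 0.0494, and adjusted p = 0.651 with an estimated correlation), while other probe sets of Mdh1 were at -0.06 and 0.05. Mdh1 encodes the cytosolic malate dehydrogenase, so it and Ckmt2 lie outside the cycle itself, and the list is wider than its name. The 74 oxidative phosphorylation genes had a median of 0.22, with 65 of them above 0 and no member past the threshold, over all probe sets or adjusted over the list alone (adjusted p = 2.83e-07, and adjusted p = 0.553 with an estimated correlation). Of 22 genes of glycogen use and glycolysis, Ldhb, the lactate dehydrogenase subunit of oxidative tissue, rose by 1.33, and 2 members passed adjusted over the list alone (median 0.22, adjusted p = 0.00275, and adjusted p = 0.553 with an estimated correlation). Of 18 fast fibre genes, Myh2, the myosin heavy chain of oxidative fast fibres, rose by 1.71 and passed adjusted over the list alone too (median 0.50, adjusted p = 1.06e-05, and adjusted p = 0.553 with an estimated correlation).

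Smaller shifts were seen in ribosomal protein genes (37 tested, median 0.16, adjusted p = 2.13e-05, and adjusted p = 0.289 with an estimated correlation), with Rps3a1 at 0.34 and Rpl7 at 0.23 past the threshold and 5 members adjusted over the list alone. Proteasome subunit genes had a median of 0.12 over 31 members, with Psmd6 at 0.26 past the threshold, also adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.287 with an estimated correlation), while the other probe set of Psmd6 was at -0.18. After quantile normalization the calls of the fast fibre (adjusted p = 0.734, median 0.00606), glycolysis (0.7, with a median of -0.00235), oxidative phosphorylation (0.614, median 0.02), citric acid cycle (0.614, median 0.002), ribosomal (0.614, median 0.03) and proteasome (0.0593) lists ended. Without the 3 triceps arrays that stood apart those of the fast fibre (0.493), glycolysis (0.331) and citric acid cycle (0.331) lists ended, with medians of 0.03, 0.05 and -0.01, and the oxidative phosphorylation and ribosomal lists had medians of 0.05 and 0.09. The fast fibre median was 0.33 without SOD1-G93A triceps replicate 2. The citric acid cycle call also ended after median centring (0.0505), with the filter at the 60th percentile (0.13), and without SOD1-G93A triceps replicates 1 (0.0812) or 2 (0.133, median 0.04), SOD1-G93A gastrocnemius replicates 3 (0.0675) or 4 (0.136, median 0.05), NTg triceps replicates 2 (0.0945) or 4 (0.0503) or NTg gastrocnemius replicate 3 (0.11).

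Genes lower in gastrocnemius belonged to no single list. Malat1, a nuclear long noncoding RNA, fell by 1.56 relative to triceps, Zfp503, a transcriptional repressor, by 1.41, Kcnc4, a voltage-gated potassium channel, by 1.39. Gpx3, the secreted glutathione peroxidase, fell by 1.26 (SE 0.16, adjusted p = 7.24e-05), Tnfaip2 by 1.23, Shisa2 by 1.12, Ces1d, a carboxylesterase, by 1.03 and Cd24a by 0.93. The list of 20 antioxidant genes did not shift (adjusted p = 0.59), with Gpx3 lower and Prdx2, a peroxiredoxin, higher by 0.44, both also adjusted over the list alone. Nor did the 23 heat shock protein genes (adjusted p = 0.831), of which Hspb7 (2.05) and Cryab (0.57), small heat shock proteins of muscle, were higher and Hsph1 (-0.67) was lower (3 higher and 2 lower adjusted over the list alone). Among 25 calcium-handling genes Atp2a2 and Casq2 (1.06), the slow calsequestrin, were higher (adjusted p = 0.0828 for the list, whose median was -0.000242 and whose mean and test pointed to higher values). For immediate early genes in gastrocnemius against triceps the adjusted p was 0.315, and 0.0228 with the mouse as a block (median -0.14). Without a block it was adjusted p = 0.803 with an estimated correlation, and without the 3 triceps arrays that stood apart the list did not pass (0.725), with a median of 0.10. Circadian clock genes did not pass (adjusted p = 0.457, median -0.07) with all arrays, and passed without those 3 arrays (0.0304, median -0.26), against adjusted p = 0.68 with an estimated correlation and all arrays. The other lists had adjusted p values between 0.204 and 0.885.

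In all, limma called 171 of 4637 probe sets (143 genes) between the muscles, 98 higher and 73 lower in gastrocnemius, and 144 of them differed the same way in all 8 mice. The calls came from these same mice, so the shared direction is no separate support for them. With each mouse as a block, so that its own 2 muscles were paired, 318 probe sets passed. Without the 3 triceps arrays that stood apart 103 passed, 82 of them among the 171. The count was 111, 99, 107, 105, 100 and 113 without SOD1-G93A triceps replicate 1, SOD1-G93A triceps replicate 2, NTg gastrocnemius replicate 1, NTg gastrocnemius replicate 2, SOD1-G93A gastrocnemius replicate 3 and SOD1-G93A gastrocnemius replicate 4, and 272 and 257 without NTg triceps replicates 3 and 4.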

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

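The tests new to this part were chosen after the result was seen, except the counts of gene lists over all splits of the mice and over exchanges of the muscles. Camera's test of the difference of effects, the estimated correlation and leaving out single arrays had been fixed beforehand. Which array to read for the slow fibre list was chosen afterwards. For array scaling, the split into numbers 1 and 2 and numbers 3 and 4 came from the data, and the bound was set before the normalized count was seen.

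Dixon's outlier test flagged several arrays against the other 3 of their group, some of them for small differences. NTg triceps replicate 2 had a mean correlation of 0.878 with its group, against 0.918 to 0.924 for the others. Proteasome subunit genes averaged 9.251 in NTg gastrocnemius replicate 3 (others 9.309 to 9.316) and 9.31 in NTg triceps replicate 2 (others 9.209 to 9.218). The adipocyte list averaged 9.64 in NTg triceps replicate 4 (others 9.506 to 9.525). Gas6 was at 8.697 in SOD1-G93A gastrocnemius replicate 3 (others 8.451 to 8.456), and Gpx3 at 10.9 in NTg triceps replicate 4 (others 10.08 to 10.13). In all, 112 groups of 4 were examined with Dixon's outlier test, whose nominal rate by chance is about 1 in 20 for normally distributed values. At that rate chance would flag about as many groups as were flagged here, so the flags alone mark no array as odd. Whether that rate holds for these measures was not tested. The genotype effect differed between gastrocnemius and triceps for extracellular matrix genes (-0.285), slow fibre genes (-0.914) and proteasome subunit genes (0.124), by camera's test of the difference, and none of these held with an estimated correlation (adjusted p = 0.882, 0.882 and 0.844 with an estimated correlation).

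Chance was set against the results by splitting the 8 mice into other groups of 4. No probe set was called in any genotype comparison, so all 35 of the 35 splits gave as many in gastrocnemius (highest other 1), in triceps (733), over both muscles (474) and for the difference of effects (0). As many gene lists as for the real genotypes were called in 26 of the 35 splits for gastrocnemius (real 1, highest other 9), 25 for triceps (3 and 10), 19 over both muscles (5 and 11) and 17 for the difference of effects (3 and 9), so chance cannot be excluded for the number of lists in any of these 4 comparisons. Of the 18 splits that divide numbers 1 and 2 evenly, as the real one does, 11, 8, 2 and 3 gave as many lists (highest other 4, 7, 8 and 4). With 18 splits no share can be under 0.0556, so they are too few for a share under 0.05. Between the muscles, 1 of 100 exchanges of the 2 muscles within mice, the real one, gave as many probe sets (171, highest other 12), so chance can be excluded for this count. For lists 1 of 100 gave as many (12, highest other 11), by a narrow margin. Of the 12 list calls 2 held with an estimated correlation. Since another exchange called nearly as many lists, the count says nothing of any single list.

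The adipocyte list was higher in SOD1-G93A over both muscles. Of the 35 splits of the mice, 9 gave as small a smallest p over the 25 lists (real 1.66e-08, smallest other 6e-19), so chance cannot be excluded, and of the 18 even splits, too few for a share under 0.05, 1 did, the real one (next 1.91e-08). More fat tissue in the SOD1-G93A samples may raise the list. The test assumed that fat tissue would raise adiponectin at least as much as the lipid synthesis genes. The mean of Fasn, Scd1 and Thrsp, chosen after their rise was seen, differed by 0.494 more than Adipoq did (exact permutation p = 0.0571 over 8 mice). This missed the threshold, and part of the gap rests on a dim signal, as Fasn averaged 5.81 in NTg gastrocnemius. Adipoq differed by 0.808 within mice numbered 1 and 2 and by 0.0611 within those numbered 3 and 4 (0.174 in gastrocnemius and -0.0522 in triceps). The lipid synthesis genes differed by 1.22 and 0.635, and Fabp4 over all mice by 0.0925 (exact permutation p = 0.4). With 2 mice per genotype in each set, more fat tissue and a change of lipid synthesis, in whichever cells, cannot be told apart here. An effect of the transgene, which could act through either, stays a hypothesis.

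Slow fibre genes were higher in SOD1-G93A triceps by camera, which did not hold at adjusted p = 0.758 with an estimated correlation. The list mean per array differed by 0.671 with an exact permutation p of 0.429 over the 8 triceps arrays, so the difference lay within the spread between samples. Myh7 was at 8.81 in SOD1-G93A triceps replicate 4, and without that array the list had a median of 0.262 and an adjusted p of 0.544. Several members lay near the bottom of the scale in triceps, such as Myh7 at a mean of 3.16 in NTg, so the list's size rests partly on dim signals. A candidate explanation is a triceps sample with more slow fibres, from the animal or from where the muscle was taken. An effect of genotype was not excluded.

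Arrays numbered 1 and 2 differed from those numbered 3 and 4 in both genotypes, and this is the split of the mice that called 733 probe sets in triceps and 474 over both muscles. With all arrays, 457 probe sets differed between these numbers, and 0 for each other way of pairing the numbers. These fits had no mouse block, so both muscles of a mouse counted as separate samples, which can raise the counts. After quantile normalization 303 were called against 0 and 0, fewer than the bound (within 1.5 times of 457) allowed, so array scaling as a part of the cause was not excluded. No label gives a batch, a day or a litter, and no biological explanation was tested. Each genotype has both kinds of number, so this structure adds spread and does not follow the genotypes.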

How the results depend on the processing

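Leaving out the 3 triceps arrays that stood apart, the constant of 16 and the replicate sets (numbers 1 and 2 against 3 and 4) were chosen after the data were seen.

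In gastrocnemius and for the difference of effects 0 probe sets were called by limma in all 34 and 33 settings, with 49 to 251 and 45 to 245 at an unadjusted p under 0.05. In triceps and over both muscles calls came in 1 setting each, replicates 3 and 4 alone (1 probe set, Myl3, and 2, Gadd45g and Tob2), with 54 to 316 and 44 to 207 unadjusted. Between the muscles the 171 calls became 318 with the mouse as a replicate block, 36 in NTg mice only, 42 in SOD1-G93A mice only (fewer samples in both), 103 without the 3 triceps arrays, 436 with the replicate set as a block, 364 in replicates 1 and 2 alone and 62 in replicates 3 and 4 alone, and 99 (without SOD1-G93A triceps replicate 2) to 272 (without NTg triceps replicate 3) with an array left out. Of the 171, 165 were also called with the mouse block and 140 after quantile normalization.

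The number of lists called in gastrocnemius, 1, became 2 with no filter, the 60th percentile filter, the replicate block, without the 3 arrays, the replicate set as a block and the set within muscle, 0 with an estimated correlation, and 1 to 4 with an array left out. In triceps 3 became 0 with an estimated correlation, 5 with the replicate block, the set as a block and the set within muscle, 2 without the 3 arrays (slow fibre genes higher, oxidative phosphorylation genes lower), and 1 to 6 with an array left out. Over both muscles 5 became 3 with no filter, 2 with the 60th percentile filter, 1 after quantile normalization, 1 with an estimated correlation, 2 without the 3 arrays, and 1 to 7 with an array left out. For the difference of effects 3 became 0 with an estimated correlation, 6 without the 3 arrays, and 1 to 6 with an array left out. Between the muscles 12 became 5 after quantile normalization, 2 with an estimated correlation and 9 without the 3 arrays (clock genes newly lower). Fast fibre genes reversed for the difference of effects without the 3 arrays (0.24, adjusted p = 0.021, against -0.02, not called, and adjusted p = 0.995 with an estimated correlation and all arrays). The cause was not tested.

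Replicate numbers do not pair mice across genotypes (correlations 0.00065 to 0.22 in gastrocnemius and 0.034 to 0.37 in triceps, own number best in 1 of 8). Apart from the counts given, the blocks changed no probe set count between genotypes. With the replicate set as a block limma's smallest adjusted p was 0.114 in gastrocnemius, 0.927 in triceps and 0.0584 over both muscles. Without it these were 0.999, 0.994 and 0.997. The replicate block added fast fibre genes in gastrocnemius and fast fibre and glycolysis genes in triceps to the lists called. None of these passed with an estimated correlation, either without a block (adjusted p = 0.831, 0.911 and 0.758) or with the replicate set as a block (0.825, 0.685 and 0.683). Of single genes over all settings, 15213 values kept direction and side of the threshold, 224 lost and 66 gained a call, 185 uncalled values changed sign, and 0 reversed. Of lists 3077 kept both, 106 lost and 74 gained a call, 217 uncalled ones changed sign and 1 reversed. Most of the single genes were picked by size or p in these same data. Only the muscle comparison had single-gene calls to lose, so the kept count of genes is no measure of robustness. Dim signals limit what can be said of the 40% of probe sets under the filter, among them all but 1 of the 8 neuromuscular junction and denervation genes in the table.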

Other observations

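All tests in this part were chosen after the result was seen.

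Many genes differed between arrays numbered 1 and 2 and those numbered 3 and 4. Of 457 probe sets, 211 were higher in numbers 1 and 2 and 246 lower, with 82 called within gastrocnemius and 361 within triceps. The fit that gave the 457 had no mouse block, and neither had the list tests over all arrays. Immediate early genes, which are switched on within minutes of a stimulus, were higher in numbers 1 and 2 (median 0.88 over 14 members, 10 of which passed, adjusted p = 1.3e-08, and adjusted p = 0.0296 with an estimated correlation), with Fos at 1.79. No other list held with an estimated correlation. Single genes picked from the values were Tsc22d3 (1.08, another probe set at -0.41), Cebpd (1.46), Mt2 (1.46), Gadd45g (1.97), Ccn2 (1.74), Ppp1r3c (1.25), Noct (1.42) and Nr1d1 (-0.96). Fast fibre genes were lower (median -0.73, 15 members passed, adjusted p = 7e-15, and adjusted p = 0.313 with an estimated correlation). So were oxidative phosphorylation (-0.18, 1.1e-07, and adjusted p = 0.487 with an estimated correlation), glycolysis (-0.26, 3.87e-05, 0.362), calcium-handling (-0.24, 0.000109, 0.262), slow fibre (-0.38, 0.0053, 0.53), citric acid cycle (-0.18, 0.00577, 0.426) and fatty acid oxidation genes (-0.16, 0.019, 0.53). Endoplasmic reticulum stress genes were higher (0.19, 0.0252, 0.487), and heat shock protein genes did not pass (0.235). The 3 triceps arrays with low Ckm (12.76 to 13.02) all carry numbers 1 or 2, so this split and those arrays overlap. The split itself came from the arrays.

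A hypothesis was that the transgene shifts both muscles alike, so that genotype differences correlate between gastrocnemius and triceps. Across probe sets, which are not independent replicates, the correlation was 0.138, and 24 of the 35 splits of the mice gave one as high (highest other 0.435). The 2 muscles come from the same mice, which may raise the correlation under other splits too, and the test leaves the hypothesis open.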
